A study of Mus musculus with 3 samples.

How the data were processed

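Single-cell RNA sequencing was done on mouse ovaries with the 10x Genomics 3′ v3 kit. Per the labels' protocols, C57BL/6 females were young (3 months old), or were given metformin at 350 mg/kg/day in drinking water for 6 months from 14 months of age, or were left untreated, with 5 mice per group. The left ovaries of 3 mice of a group were pooled before dissociation in enzymes for 30 min at 37 °C. The suspension was passed through a 40 µm strainer, which removes oocytes, red cells were lysed, and the cells were sorted by flow cytometry with a gate that the labels do not give. Cells carried MULTI-seq tags, which are lipid-anchored DNA labels that mark the origin of a cell in a mixed library, and were sequenced on a NextSeq 500.

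The authors deposited 1 table of whole-number UMI counts for 14353 cells and 18789 genes, 40 of which had no UMI, over 3 multiplexed pools called A, B and C. Reads were processed with Cell Ranger 3.0.2 against GRCm38, also called mm10, per the submitters' processing notes. Per the file headers, the other deposited columns used here are, for each cell, its pool, its tag, its condition and its cell type name, which are other than numbers, and the percent of its UMIs on mitochondrial genes. Recomputing the UMI total and the mitochondrial percent from the counts gave no difference in any cell (tolerance 1e-06 for the percent). The lowest total of a deposited cell was 500 UMIs and the highest mitochondrial percent was 20.0. No further cell was left out. The column headers name Seurat steps, whose version is not given in the sources used here. The deposited doublet column held no doublet, and no doublet caller was run. Doublets of cells with the same tag cannot be seen from tags.

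Each of the 3 tags went with 1 condition: young, aged untreated, and aged with metformin from 14 months, called the prevention arm. The age of the untreated aged condition is not stated for its cells. A condition is therefore taken as 1 suspension and 1 sample, and its cells in pools A, B and C as technical repeats. The labels do not say how cells were divided over the pools, so it is open whether the pools hold different mice. Tags do not name single mice, so no test was run, no p-value is given, and the edgeR and DESeq2 fits foreseen for tags of single mice were not run. No cells named as given metformin from 18 months, or as untreated at 14 months, were analysed here.

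Shares of cells are given with exact Clopper-Pearson 95% intervals, and ratios of shares or of counts with exact intervals conditional on the sum. All such intervals cover counting error only. Comparing pool with pool within 1 condition, these intervals excluded a log2 ratio of 0 in 7.22% to 23.8% of genes across 6 cell types, so they understate the spread between repeats. Within a cell type, UMIs were summed per condition and scaled to the total of the summed UMIs as CPM. A count of 0 was replaced by 3 UMIs for a bound, and for a share of 0 the limit given is 3 counts over the total. Bounds from 3 UMIs are stricter than the limits of the exact 95% intervals. With age those log2 limits were -3.10 for Sox11 in fibroblasts, -3.38 for Ctse in macrophages and -5.05 for Il2 in NK cells. For Cdkn2a in macrophages with metformin the limit was 3.58. Both cell classes whose name begins with Macrophage were summed.

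Cell types are those the authors deposited (20 names). The rule for named genes was set before the data were examined. It takes fibroblasts, macrophages and the next largest classes by the cells of the smaller condition, up to 4 classes per comparison with at least 100 cells in each condition. Genes with at least 50 UMIs over both conditions were ranked by the bound of the log2 ratio interval nearest 0. The 4 highest and 4 lowest were named where that bound lay beyond 1, or failing that beyond 0.58, and the sign was shared by every pool with at least 20 cells from both conditions. Mitochondrial, ribosomal protein and haemoglobin genes, Malat1, Xist, gene models and the 20 top markers of other classes were left out. Col1a1, Col1a2 and Col3a1 in fibroblasts and Spp1 in macrophages were named in any case. Members of gene lists are named among the 4 with the most UMIs whose interval excluded 0.

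A total of 22 gene lists and 24 lists of cell type markers were also set before the data were examined. For genes with at least 20 UMIs, the median log2 CPM ratio of a list, with 1 UMI added to each count, was placed among 10000 random lists of the same size matched on mean CPM in 20 bins. Members of a list were counted as higher or lower by the sign of their ratio, whether or not its interval included 0. A list is called above or below the random lists when it lay outside their central 95%, from percentile 2.5 to percentile 97.5. Which of these lists and members are described followed a rule set after seeing the data: for each class, up to 2 members are given for the 4 lists with the largest medians. The follicular granulosa cells were also added after seeing the data.

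The steps were tested on simulated data, with counts drawn for the real genes and 200 genes shifted by known amounts. The draws carried counting error only, the same error that the intervals cover. A shifted gene counts as recovered when its interval excluded no change in the direction of the shift, whatever the size found. In fibroblasts, a log2 ratio of 1 was recovered for 95% of shifted genes in the simulated age comparison (12765 genes) and 92% in the metformin comparison (11894 genes). In macrophages the values were 79% (10973 genes) and 91% (8185 genes). Pools of the real data spread wider than counting error, so these percentages check the steps and do not give the recovery in the real data.

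Cells were also clustered again from the counts with scanpy 1.11.5 and igraph 0.11.9, on 2000 variable genes and 30 principal components with 15 neighbours at Leiden resolution 0.8. A shared-neighbour graph took the place of scanpy's own neighbour graph. Clusters were called "like" a cell type from the marker lists, and otherwise left without a name. Gene positions are from the GENCODE annotation of GRCm38. Alternatives were each pool left out in turn, other filters on cells and genes, other denominators, TMM scaling in edgeR 4.0.16 under R 4.3.3, the mean of each cell's CPM, thinning of cells to 1000 UMIs, and rebuilt classes. Those added after seeing the data left out the cell with the most UMIs of a gene, took 1 macrophage class alone, summed fibroblasts with myofibroblasts, or left fibroblasts out of the denominator. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.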

Results

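Cells from ovaries of young mice, untreated aged mice and aged mice given metformin were profiled together in 3 multiplexed 10x pools. After assignment by tag there were 7620 young cells (48628104 UMIs, median 5278 per cell), 2979 aged cells (11779829 UMIs, median 3034) and 3754 metformin cells (13906645 UMIs, median 2752). Pools A, B and C held 26123604, 24597312 and 23593662 UMIs from 5031, 4471 and 4851 cells. The labels describe 1 suspension of 3 ovaries per condition and do not say how cells were divided over the pools. Pools were therefore taken as technical repeats, no difference was tested, and intervals are 95% intervals for counting error only. Counts of genes of a list that were higher or lower go by the sign of the ratio alone. Whether the pools hold different mice, and so are replicates, is open. The free RNA of a pool is shared by all of its conditions.

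The first comparison, of untreated aged with young ovaries, addresses how the cell makeup and expression of the ovary differ with age, at which fibrosis is known to build up. Fibroblasts, the stromal cells that make most of the collagen, were 43.6% of aged cells (interval 41.8 to 45.4) and 26.0% of young cells (25.1 to 27.0), a ratio of 1.67 (1.56 to 1.80). T cells of both classes together made up 14.1% against 4.12%, a ratio of 3.43 (2.96 to 3.98). Macrophages of both classes were lower, at 6.88% against 21.7% (ratio 0.317, 0.273 to 0.367). Follicular granulosa cells, which surround the growing oocyte, were 4.40% against 13.1% (0.336, 0.278 to 0.404), and the cells deposited as luteinized granulosa 2.05% against 10.3% (0.199, 0.150 to 0.258). The top 20 markers of the latter class held 3 theca, 3 luteal and 0 granulosa markers, and after clustering the cells again 821 of its cells fell in a theca-like cluster and 78 in a luteal-like one. B cells of the class named I (4.13% against 1.90%) and mast cells (0.873% against 0.171%) had higher shares in the aged condition, and vascular endothelium (2.32% against 3.62%) and dendritic cells of class I (1.81% against 3.95%) lower ones. The vascular endothelium ratio was 0.389 in pool A. In pools B (0.756, 0.482 to 1.15) and C (0.873, 0.525 to 1.40) its interval includes 1. In pool A the intervals for B cells of class I (1.27, 0.779 to 2.05) and mast cells (2.38, 0.684 to 8.56) include 1 too. Without pool A the mast cell ratio was 7.93 in place of 5.12. NK cells and innate lymphoid cells, at 6.55% and 5.68%, had a ratio whose interval includes 1 (1.15, 0.968 to 1.37). The age ratio of fibroblasts was 1.99 in pool A, 1.49 in pool B and 1.31 in pool C. Shares also depend on the strainer, on dissociation and on the sorting gate.

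**Figure D1:**
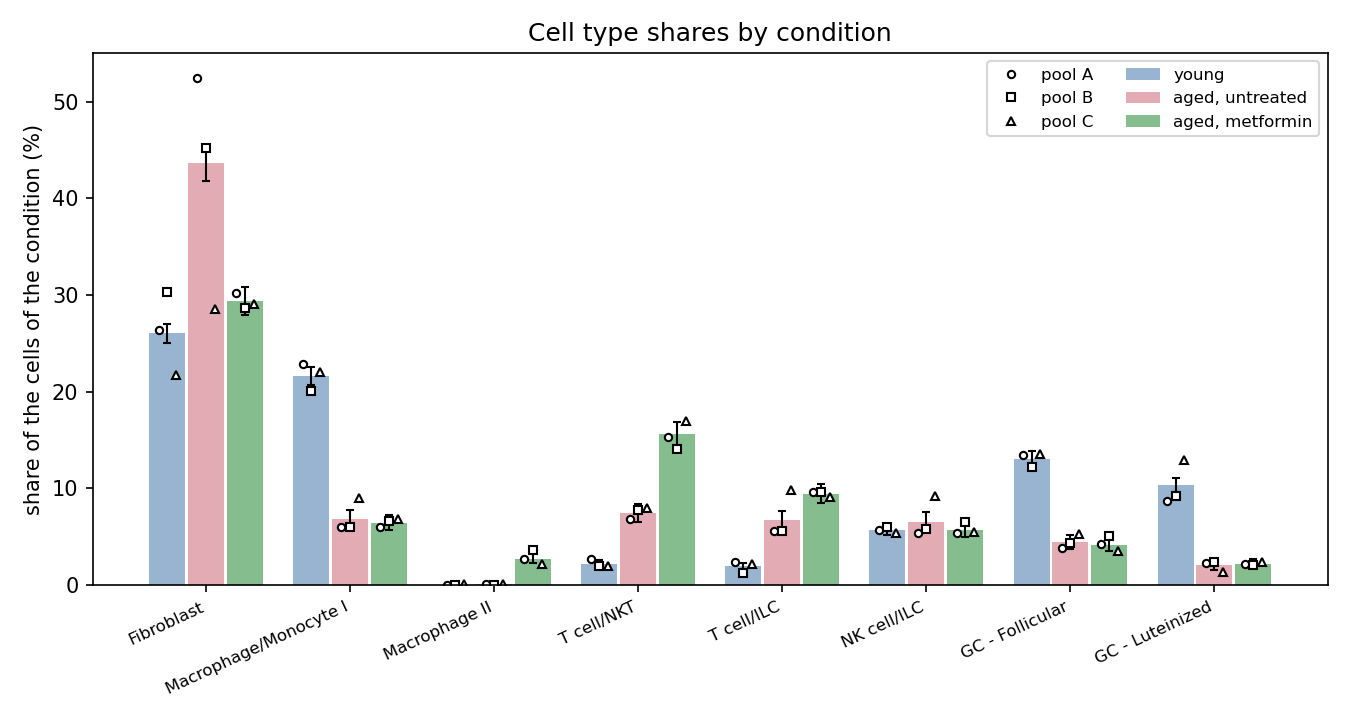
Share of the cells of each condition (vertical axis, %) for 8 cell types, with young in blue, aged untreated in red and aged with metformin in green; bars are all pools with 95% Clopper-Pearson intervals, and circles, squares and triangles are pools A, B and C. Aged fibroblasts lie at 52.4% in pool A and 28.5% in pool C, and Macrophage II bars reach 2.72% with metformin and 0.067% in the aged condition.

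In aged fibroblasts the main collagen genes were lower than in young ones. Col1a1 and Col1a2, which encode the chains of type I collagen, were at 485 and 1304 CPM against 680 and 1736 CPM in young, with log2 ratios of -0.49 (-0.55 to -0.43) and -0.41 (-0.45 to -0.38). Col3a1, the chain of type III collagen, was at 721 against 1156 CPM (-0.68, -0.73 to -0.63). In GRCm38, Col1a1 lies on chromosome 11 from 94936224 to 94953042, Col1a2 on chromosome 6 from 4504814 to 4541544, and Col3a1 on chromosome 1 from 45311538 to 45349706, each annotated as a protein-coding gene. All 3 were lower in each pool. After clustering the cells again, a choice made after seeing the data, a stromal cluster led by Col1a1 held 9.65% of young and 4.03% of aged cells. Within its deposited fibroblasts the ratios were -0.11 for Col1a1, -0.02 for Col1a2 and -0.04 for Col3a1. They were -0.14, -0.00 and -0.38 in those of a cluster led by Lrat and -0.36, -0.12 and -0.90 in one led by Kcnk2, and these genes took part in forming the clusters. Of 29 measured genes of fibrillar collagen and matrix, 19 were lower and 10 higher, with a median of -0.32, below the random lists. Dcn, the small proteoglycan decorin, was higher (0.78, 0.75 to 0.80).

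Other gene groups of aged fibroblasts differed too. Cell cycle genes were lower for 15 of 16 members (median -0.95), including Top2a, the DNA topoisomerase of dividing cells (-1.21, -1.43 to -1.0), and Pcna, the replication clamp (-0.36, -0.54 to -0.18). All 11 myofibroblast genes were lower (median -0.68), with the intermediate filament gene Vim at -0.38 (-0.43 to -0.33) and the tropomyosin gene Tpm1 at -0.26 (-0.30 to -0.23). MHC class II genes, which present antigen to T cells, were higher for 7 of 8 members (median 0.69), with Cd74 at 0.54 (0.42 to 0.65) and H2-Ab1 at 0.78 (0.65 to 0.90). In the same cells the markers of macrophages had a median of -0.62, of monocytes -0.73 and of T cells 0.40. Dissociation stress and immediate early genes were higher for 16 of 19 members (median 0.41), with Fos at 0.41 (0.40 to 0.43) and Jun at 0.53 (0.51 to 0.55). Smooth muscle markers had a median of -0.80 in these cells, blood endothelium markers -1.34, pericyte markers -0.50, theca markers -0.56 and luteal markers -0.25. Of 22 lists, 6 lay above and 6 below the random lists. The others outside them were protease inhibitors (0.39), classical inflammatory cytokines (0.36), ovarian adhesion and follicle ligands (0.32) and antioxidant genes (0.12) above, and basement membrane (-0.40), steroidogenesis (-0.18) and nuclear oxidative phosphorylation (-0.14) below. The antioxidant median was -0.02 without pool A. After clustering the cells again, a cluster without a name, picked after seeing the data, held 72 of the deposited fibroblasts, over all conditions. It was led by Hhip, with Top2a and the theca marker Ptch1 among its leading genes. Whether these cells carry the cell cycle or theca marker values was not tested.

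The named fibroblast genes with the largest ratios included Cilp, a matrix protein of cartilage (2.05, 1.42 to 2.70), the diacylglycerol kinase Dgkb (1.96, 1.1 to 2.88), Ly6h (1.40, 1.09 to 1.70) and the sterol enzyme Sc5d (1.25, 1.03 to 1.47). Sox11, a transcription factor of developing tissues, had 0 UMIs in aged fibroblasts and 67 in young ones, which bounds the log2 ratio at -3.43 or lower when 3 UMIs stand for 0. The imprinted gene Mest was lower (-2.17, -2.59 to -1.78), as were the renin gene Ren1 (-5.20, -10.52 to -2.68, 1 against 76 UMIs) and the potassium channel subunit gene Kcne4 (-4.12, -7.20 to -2.22, 2 against 72 UMIs). The young UMIs of Ren1 were in 12 of 1984 fibroblasts, with 32.9% of them in 1 cell. With myofibroblasts added to the fibroblasts, Dgkb stood at 0.18, Kcne4 at -1.39 and Ren1 at -5.81, and with cells thinned to 1000 UMIs Cilp stood at 1.46 and Mest at -2.83. Without pool A, Ren1 was at -4.14 and Kcne4 at -3.29, without pool C Kcne4 was at -4.89, and as the mean over cells Ren1 was at -4.24.

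Aged macrophages had higher monocyte genes and lower tissue macrophage genes than young ones. Chil3, a chitinase-like protein of monocytes and alternatively activated macrophages, was at 909 against 84.0 CPM (3.44, 3.30 to 3.57). The granule protease Prtn3 (5.03, 4.10 to 6.05), the matrix proteoglycan versican gene Vcan (3.49, 3.00 to 3.97) and Dmkn (4.31, 3.59 to 5.07) were higher. The chemokine Ccl8 (-4.18, -5.19 to -3.34), the growth factor Bmp2 (-2.97, -3.84 to -2.21) and Top2a (-4.20, -6.48 to -2.64) were lower, and the protease Ctse had 0 UMIs in aged and 399 in young macrophages, a log2 ratio of -3.68 or lower. The monocyte marker list had a median of 1.67 and the macrophage marker list -0.87 in these cells. Different clusters made up the class: after clustering the cells again, a macrophage-like cluster led by Pf4 held 16.6% of young and 2.79% of aged cells, and a monocyte-like cluster led by Chil3 held 3.01% and 3.39%. With thinned cells Prtn3 stood at 5.92, Chil3 and Vcan at 2.73, Bmp2 at -3.68 and Top2a at -1.77, and as the mean over cells Bmp2 stood at -3.71 and Top2a at -3.22. Without pool A, Dmkn was at 3.24 and Ccl8 at -4.97, without pool B Top2a was at -5.30, and without pool C Dmkn was at 5.14, Bmp2 at -3.71 and Top2a at -3.59.

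Resident or alternatively activated macrophage genes were lower for 10 of 12 members (median -1.34), with the selenium carrier Selenop at -1.30 (-1.41 to -1.20) and the chemokine Pf4 at -1.77 (-1.92 to -1.62). All 16 cell cycle genes were lower (median -2.01), with Pcna at -0.59 (-0.90 to -0.29) and Mcm3 at -2.06 (-2.94 to -1.3). Ovarian adhesion and follicle ligand genes were lower for 7 of 8 (median -1.50), with Igf1 at -1.47 and Igfbp4 at -2.11, and protease inhibitors for 6 of 8 (-1.12), with Timp2 at -1.08. Cholesterol biosynthesis genes were higher for 13 of 17 (median 1.01). Of 22 lists 3 lay above and 12 below the random lists. Glycolysis was above (0.35), and senescence (-0.47), MHC class II (-0.27), interferon response (-0.24) and dissociation stress (-0.20) were below. Basement membrane (-1.0), myofibroblast (-0.77), collagen and matrix (-0.67) and steroidogenesis (-0.64) lists were below too, in cells where the markers of stromal fibroblasts had a median of -0.66, of smooth muscle -1.06 and of luteal cells -1.54. With 5 UMIs added to each count the medians of basement membrane (0.48), collagen and matrix (0.05) and steroidogenesis (0.51) were above 0, and those of cell cycle (-1.31), adhesion and follicle ligands (-0.83) and protease inhibitors (-0.49) nearer to 0. With thinned cells Mcm3 stood at -3.01, and over genes with at least 100 UMIs the steroidogenesis median was -1.28.

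Spp1 encodes osteopontin, a secreted protein of macrophages in fibrotic tissue, and lies on chromosome 5 from 104435118 to 104441050. It was at 2680 CPM in aged and 604 CPM in young macrophages (2.15, 2.09 to 2.21). Only 30 of 205 aged macrophages had a UMI of it, against 303 of 1652 young ones, and 1 aged cell held 22.4% of its aged UMIs. Median depths of these macrophages were 4912 and 5904 UMIs. Among T cells, given for comparison only, 6 of 421 aged and 6 of 314 young cells had a UMI of it (1.43% and 1.91%). Their median depths were 1892 and 2575 UMIs. The log2 ratio was 2.92 in pool A, -0.49 in pool B and 2.10 in pool C. Of 17 genes of the profibrotic Spp1 macrophage list, 10 were higher and 7 lower (median 0.45, above the random lists), with the galectin Lgals3 at 0.72 (0.66 to 0.78) and the lipid carrier Apoe at -0.94 (-0.97 to -0.91).

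**Figure D2:**
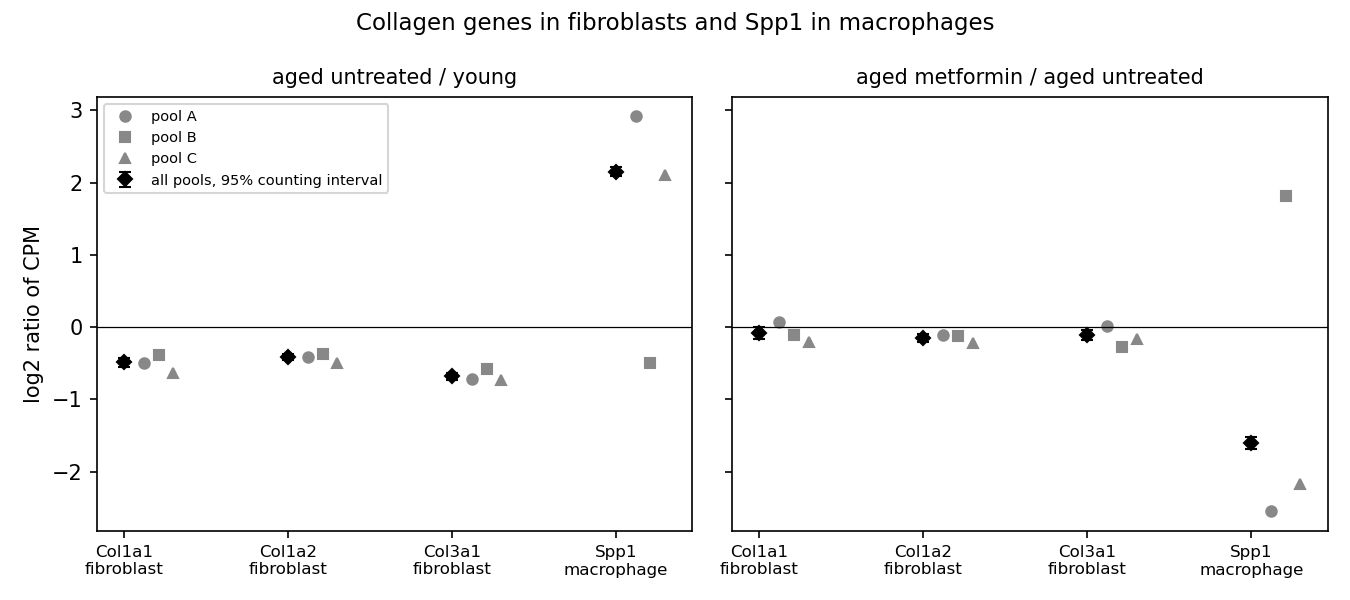
Log2 ratio of CPM (vertical axis) for Col1a1, Col1a2 and Col3a1 in fibroblasts and Spp1 in macrophages, aged over young on the left and metformin over untreated aged on the right; diamonds are all pools with 95% counting intervals, grey circles, squares and triangles are pools A, B and C. The collagen genes lie between -0.41 and -0.68 with age, and Spp1 in pool B lies on the other side of 0 from pools A and C in both panels.

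NK cells and innate lymphoid cells had higher Phactr3 (1.74, 1.05 to 2.46), Lyst, a gene of lysosomal granule traffic (1.14, 0.60 to 1.68), and Emb (0.88, 0.60 to 1.17) in the aged condition. Their cell cycle genes were lower for 11 of 14 members (median -1.56), among them Top2a (-3.81, -6.11 to -2.22) and Ube2c (-4.78, -10.11 to -2.25, 1 against 65 UMIs, of which 47.7% were in 1 cell), while Mcm6 was higher (0.80, 0.12 to 1.47). The histone gene Hist1h1b was also lower (-3.27, -4.92 to -2.01). Il2 had 0 UMIs in aged and 291 in young cells (-5.36 or lower), but 96.2% of the young UMIs came from 1 cell, and without it the bound was -0.64 or lower. Interferon response genes were lower for 11 of 12 (median -0.58), with Bst2 at -0.56 (-1.08 to -0.08) and Ifitm3 at -0.60 (-1.16 to -0.06). T cell markers had a median of -0.92 there. Cytokine genes were lower for 4 of 6 (median -0.22), with Ccl5 at -0.30 and Ccl3 at -0.15. The collagen list had a median of -0.37 and Col3a1 stood at -0.94, values that were 0.20 and 0.37 without pool B, and stromal fibroblast markers had a median of -0.30. After clustering the cells again, a stromal fibroblast-like cluster led by Sfrp1 held 25 cells of this class, over all conditions. It also held 13 fibroblasts and 12 T cell/NKT cells. Whether these cells carry the collagen values was not tested. Dissociation stress genes (-0.19) lay below and mitochondrially encoded genes (0.16) above the random lists, as 1 of 21 lists above and 5 below. The cell cycle median was -0.92 without pool A and -0.78 with 5 UMIs added, Top2a ranged from -5.17 (without pool B) to -2.97 (without pool A), Ube2c was at -4.05 without pool C and -3.86 without the top cell, and Col3a1 was at -2.04 without pool A and -0.17 without 1 cell. With thinned cells Top2a stood at -3.17, Ube2c and Hist1h1b at -2.65, Ifitm3 at -2.26 and Col3a1 at -2.31, and as the mean over cells Top2a stood at -3.14, Ube2c at -3.25 and Hist1h1b at -2.60.

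The class named Myofibroblast II expresses smooth muscle and pericyte genes. In the aged condition it had higher Ppp1r3a, a glycogen-targeting subunit of protein phosphatase 1 (4.17, 3.02 to 5.56), the neuropeptide Y receptor Npy1r (1.39, 0.94 to 1.84), Pcp4l1 (1.04, 0.90 to 1.18) and the transcription factor Klf2 (0.85, 0.77 to 0.94). The pericyte gene Steap4 (-2.71, -3.64 to -1.91), Stc1 (-3.92, -6.99 to -2.02, 2 against 81 UMIs), Thy1 (-4.43, -9.76 to -1.90, 1 against 58 UMIs) and Fabp4 (-4.71, -10.03 to -2.18, 1 against 70 UMIs, of which 54.3% were in 1 cell) were lower. Basement membrane genes were lower for 10 of 12 (median -1.46), with the type IV collagen genes Col4a1 at -1.50 (-1.68 to -1.33) and Col4a2 at -1.43 (-1.69 to -1.17). Collagen and matrix genes were lower for 23 of 24 (median -0.95), and matrix proteases for 7 of 11 (-1.0), with Ctsl at -1.03 and Adamts5 at 0.86. Pericyte markers had a median of -1.33 in these cells, stromal fibroblast markers -0.99 and smooth muscle markers 0.11. After clustering the cells again, 578 cells of this class fell in a smooth muscle-like cluster, over all conditions. Another 117 fell in a pericyte-like cluster with Steap4 and Col4a1 among its leading genes. A shift in this mix and a change within cells were not told apart. Above the random lists were also cytokines (0.55), dissociation stress (0.51) and mitochondrially encoded genes (0.30), and below them interferon response (-0.53) and antioxidant genes (-0.38). Without pool A, Ppp1r3a was at 3.56, Steap4 at -3.70, Col4a2 at -2.11 and Fabp4 at -3.61, without pool B Thy1 was at -3.72, and without pool C Ppp1r3a was at 5.17 and Fabp4 at -4.05. With thinned cells Stc1 stood at -2.58, Thy1 at -2.36 and Col4a1 at -2.53, as the mean over cells Thy1 at -6.03, Fabp4 at -3.07 and Col4a1 at -2.13, and without 1 cell Fabp4 at -3.58.

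In the same class, gene groups of cell division and antigen presentation rested on single pools. Cell cycle genes were higher in aged Myofibroblast II for 8 of 10 (median 1.57), but the median was -2.06 without pool B and 5.53 without pool C. Cenpf, a kinetochore protein gene, stood at 3.91, at -1.84 without 1 cell, -1.60 without pool B and 7.09 without pool C. Ube2c, a ubiquitin-conjugating enzyme of mitosis, stood at 4.94, and at 7.14 without pool C. With thinned cells these genes stood at 1.40 and 2.40, and as the mean over cells at 3.02 and 2.72. All 5 MHC class II genes were lower (median -1.55), with H2-Aa at -1.77 and Cd74 at -1.65, but the median was 0.60 without pool C and -0.90 with 5 UMIs added. Cd74 was at -2.46 without pool B, 0.54 without pool C and -0.49 without 1 cell. H2-Aa was at -1.01 without pool C, -1.07 as the mean over cells and -0.99 without 1 cell.

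The second comparison, of metformin begun at 14 months with the untreated aged condition, addresses how the aged ovary differs with the drug, a biguanide used against type 2 diabetes. The age of the untreated aged condition is not stated for its cells, so a difference in age beside the drug is open. Fibroblasts were 29.4% of metformin cells (27.9 to 30.8) and 43.6% of aged cells, a ratio of 0.673 (0.621 to 0.730). This ratio was 0.577 in pool A, 0.634 in pool B and 1.02 in pool C, where 28.5% of aged and 29.0% of metformin cells were fibroblasts. T cells named T cell/NKT were 15.6% against 7.42% (2.10, 1.80 to 2.47) and those named T cell/ILC 9.43% against 6.71% (1.40, 1.18 to 1.68), and immune cells as a whole 52.6% against 37.5% (1.40, 1.3 to 1.51). In pool C the ratio was 0.930 (0.698 to 1.24) for T cell/ILC and 1.06 (0.940 to 1.20) for immune cells, against 1.73 and 1.64 in pool A and 1.73 and 1.54 in pool B. Taken as a share of immune cells, the ratio for T cell/ILC was 1.0. The class named Macrophage II held 102 of 3754 metformin cells (2.72%, 2.22 to 3.29), 2 of 2979 aged cells (0.067%, 0.008 to 0.242) and 3 of 7620 young cells, a ratio of metformin to aged of 40.5 (10.9 to 339; 24.3 without pool B and 66.6 without pool C). Class Macrophage/Monocyte I was 6.45% against 6.81%, a difference within the interval of the ratio (0.946, 0.782 to 1.15). Both macrophage classes together stood at 1.33 (1.12 to 1.59), and at 0.949 when taken as a share of immune cells. B cells of class II, which carry plasma cell genes such as Jchain, were 1.15% against 0.201% (5.69, 2.41 to 16.3; 9.69 without pool A), Myofibroblast I cells 1.73% against 2.79% (0.621, 0.442 to 0.870) and lymphatic endothelium 0.426% against 0.973% (0.438, 0.222 to 0.833). Follicular granulosa cells and the class deposited as luteinized granulosa had ratios of 0.945 (0.744 to 1.20) and 1.07 (0.757 to 1.51).

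In fibroblasts, collagen genes differed little between metformin and untreated aged ovaries. Col1a1 was at 459 against 485 CPM (-0.08, -0.16 to 0.00), Col1a2 at 1174 against 1304 CPM (-0.15, -0.20 to -0.10) and Col3a1 at 666 against 721 CPM (-0.11, -0.18 to -0.05; 0.03 with thinned cells and 0.04 as the mean over cells). Col1a1 and Col3a1 were on the other side of 0 in pool A, at 0.06 and 0.02. Within rebuilt clusters, a choice made after seeing the data, Col1a1 stood at 0.49 in the cluster led by Col1a1. It stood at -0.23 and -0.24 in those led by Lrat and Kcnk2, and the last part gives the other collagen genes. Of 28 measured genes of collagen and matrix, 13 were higher and 15 lower, with a median of -0.01 at percentile 41.4 of the random lists, and the proteoglycan Lum stood at 0.09 (0.03 to 0.15).

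Named fibroblast genes that were higher with metformin were the protocadherin Pcdh10 (1.72, 0.81 to 2.72), Castor1, the arginine sensor of the mTORC1 pathway (1.40, 0.68 to 2.16), Olfm2 (1.26, 0.59 to 1.96) and the cyclin Ccnb1 (1.56, 0.76 to 2.41), which had 41.3% of its metformin UMIs in 1 cell. Lower were the eosinophil chemokine Ccl11 (-2.38, -3.58 to -1.35), the collagen chain Col6a5 (-1.37, -1.68 to -1.06), the heat shock gene Hspa1b (-1.31, -1.70 to -0.94) and Spry1, an inhibitor of growth factor signalling (-1.31, -1.80 to -0.85). These genes were named at the bound of 0.58. Between pools of 1 condition up to 93 fibroblast genes lay beyond that bound. Cholesterol biosynthesis genes were higher for 15 of 18 members (median 0.29), with Srebf2 at 0.52 (0.11 to 0.93) and Hmgcs1 at 0.30 (0.06 to 0.54; -0.03 with thinned cells). Cell cycle genes were higher for 10 of 16 (0.32), with Top2a at 0.28 and Cenpf at -0.25. All 4 cytotoxic lymphocyte genes were higher (0.49), with Ccl5 at 0.77 and Nkg7 at 0.78, values that for the list and Nkg7 were -0.09 and -0.28 without pool A, and Nkg7 was at -0.12 with thinned cells and 0.12 as the mean over cells. T cell markers had a median of 0.55 in the same fibroblasts. MHC class II genes were lower for 7 of 8 (-0.21; 0.01 without pool B), with Cd74 at -0.16 (0.01 without pool B) and H2-Ab1 at -0.31. Of 22 lists 3 lay above and 6 below the random lists, the others below being protease inhibitors (-0.19), dissociation stress (-0.16, 17 of 19 members lower), myofibroblast (-0.13), senescence (-0.12) and interferon response (-0.12). Smooth muscle markers had a median of -0.21 in these cells and pericyte markers -0.42. With myofibroblasts added, Ccnb1 stood at 0.51 and Spry1 at -0.46, as the mean over cells Ccnb1 at 2.38 and Ccl11 at -1.29, and without 1 cell Ccnb1 at 0.80. Without pool A, Pcdh10 was at 1.05 and Ccl11 at -1.77, without pool B Pcdh10 was at 2.35 and Col6a5 at -2.0, and without pool C Ccl11 was at -3.05.

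Macrophages of the metformin condition included the 102 cells of Macrophage II among 344, and several genes differed through that class. The endothelial lipase gene Lipg had 342 UMIs against 1 (7.62, 5.13 to 12.9) and Klra17 191 against 2 (5.78, 3.90 to 8.83). In Macrophage/Monocyte I alone these were 2.02 and -1.30. Ccl8 was higher (4.54, 3.69 to 5.55), and Cdkn2a, a cell cycle inhibitor and marker of senescence, had 79 UMIs against 0, a log2 ratio of 3.92 or higher. The Cdkn2a UMIs were in 34 of 344 metformin macrophages, and whether these were Macrophage II cells is not given here. The collagenase Mmp13 (-4.50, -6.17 to -3.21), the elastase Mmp12 (-3.26, -3.90 to -2.67) and Chil3 (-2.33, -2.52 to -2.15) were lower. Ctsk, a collagen-degrading cathepsin, was at -3.39 (-4.36 to -2.53), but 85.9% of its aged UMIs came from 1 cell, and it stood at -0.57 without that cell, -1.13 without pool C and -1.14 with thinned cells. Spp1 was at 882 against 2680 CPM (-1.60, -1.69 to -1.51). It had UMIs in 39 of 344 metformin macrophages at a median depth of 4726 UMIs, and 38.3% of its metformin UMIs were in 1 cell. Its log2 ratios were -2.54, 1.81 and -2.17 in pools A, B and C and -2.36 without pool B. Among T cells, given for comparison only, 12 of 940 metformin cells had a UMI of it (1.28%, at a median depth of 1896). Those metformin T cells held 165 UMIs of Spp1, against 12 UMIs in 421 aged T cells. In T cells its CPM was thus higher with metformin, the opposite direction to macrophages. How the 165 UMIs were spread over cells is not given here. The Spp1 macrophage list had 6 members higher and 11 lower (median -0.20; 0.11 in Macrophage/Monocyte I alone), with Lgals3 at -0.66 and Apoe at -0.24 (0.18 in that class alone). Without pool A, Ccl8 was at 5.46, without pool B Lipg was at 6.76, Klra17 at 4.88 and Mmp12 at -7.19, and without pool C Lipg was at 7.03, Ccl8 at 3.51 and Mmp12 at -2.66. Lipg stood at 5.30 with thinned cells, Ccl8 at 3.95 as the mean over cells and Mmp12 at -2.67 without 1 cell.

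Among macrophage gene groups under metformin, cell cycle genes were higher for 11 of 12 (median 1.47), with Mki67 at 2.42 (1.43 to 3.60) and Top2a at 3.86 (2.26 to 6.17). In Macrophage/Monocyte I alone the list had a median of 0.17 and these genes stood at 0.11 and 1.28, and with thinned cells at 0.86 and 1.09. Top2a was at 4.77 without pool B and 2.92 as the mean over cells. All 6 protease inhibitors were higher (1.21), with Timp2 at 0.36. Collagen and matrix genes were higher for 11 of 13 (1.12; 1.79 without pool B), although the most abundant members, fibronectin Fn1 (-0.65) and thrombospondin Thbs1 (-0.70), were lower, and stromal fibroblast markers had a median of 0.87 in these cells. Cholesterol biosynthesis genes were lower for 12 of 13 (-0.72). All 10 MHC class II genes were lower (-0.50), as were 16 of 18 dissociation stress genes (-0.48), 11 of 15 interferon genes (-0.45), 11 of 16 cytokines (-0.40; 0.05 in Macrophage/Monocyte I alone), 8 of 10 matrix proteases (-0.51) and 12 of 15 glycolysis genes (-0.23). Senescence (0.53), resident macrophage (0.51), antioxidant (0.40), mitochondrially encoded (0.23) and nuclear oxidative phosphorylation genes (0.15; -0.00 in Macrophage/Monocyte I alone) lay above the random lists. Monocyte markers had a median of -0.91 and macrophage markers 0.03.

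In T cell/NKT, the transcription factor gene Cebpd (2.34, 1.16 to 3.83) and the transcriptional cofactor gene Lmo1 (2.03, 0.91 to 3.39) were higher with metformin, and Lgals3 (-1.70, -2.25 to -1.15), Rhob (-1.63, -2.31 to -0.96; -0.75 without 1 cell that held 46.5% of its aged UMIs), Capg (-1.31, -1.94 to -0.67) and Klf2 (-1.0, -1.18 to -0.81) were lower. All 7 inflammatory cytokine genes were higher (median 1.07), with the chemokines Ccl5 at 0.12 (0.08 to 0.15) and Ccl4 at 0.50 (0.36 to 0.64; -0.03 without pool B). TGF-beta pathway genes were lower for 8 of 12 (-0.33; 0.22 without pool A and 0.10 over genes with at least 100 UMIs), with Tgfb1 at -0.63 and Id3 at 0.77. Senescence genes were higher for 5 of 8 (0.31; -0.06 with 5 UMIs added), with Cdkn2c at -1.24 and Cxcl1 at 3.58 (1.0 to 8.93, 31 against 1 UMI). MHC class II genes (0.30) lay above and dissociation stress genes (-0.22) below the random lists. NK cell markers had a median of -0.74, stromal fibroblast markers -0.47 and monocyte markers 0.37. Without pool A, Cdkn2c was at -0.65, without pool B Cxcl1 was at 2.74, and without pool C Rhob was at -1.01, Id3 at 1.64 and Cxcl1 at 2.59. With thinned cells Cebpd stood at 1.32, Rhob at -0.97, Cdkn2c at -2.20 and Cxcl1 at 1.39, as the mean over cells Lmo1 at 1.39, Rhob at -0.86 and Cxcl1 at 1.82, and without 1 cell Cxcl1 at 2.88.

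In T cell/ILC, the noncoding RNA AW112010 was higher (0.76, 0.59 to 0.93), and the cytokine Il17a (-1.65, -2.07 to -1.24; -2.49 without pool C), the lipid droplet gene Hilpda (-1.25, -1.62 to -0.89), Spty2d1 (-1.29, -1.76 to -0.84) and Jun (-0.93, -1.14 to -0.73) were lower with metformin. All 16 dissociation stress genes were lower (median -0.61), with Junb at -0.61 and Jund at -0.49. Nuclear oxidative phosphorylation genes were higher for 21 of 26 (0.20), with Ndufa4 at 0.26 (0.04 to 0.49) and Atp5l at 0.24 (0.01 to 0.48). Cytokines were lower for 4 of 6 (-0.64; 0.32 without pool C), with Tnf at -1.02 (-1.52 to -0.52) and Cxcl2 at -1.35 (-0.35 without pool C, -1.94 with thinned cells). Monocyte markers had a median of -0.47 in these cells. The 3 measured collagen and matrix genes had a median of -2.23, with Dcn at -2.54 (8 against 28 UMIs) and Sparc at -2.41 (5 against 16 UMIs). Dcn was at -0.84 with thinned cells and -1.55 without 1 cell, and Sparc at -0.80 without pool C, -1.25 with thinned cells, -1.13 as the mean over cells and -0.43 without 1 cell.

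**Figure D3:**
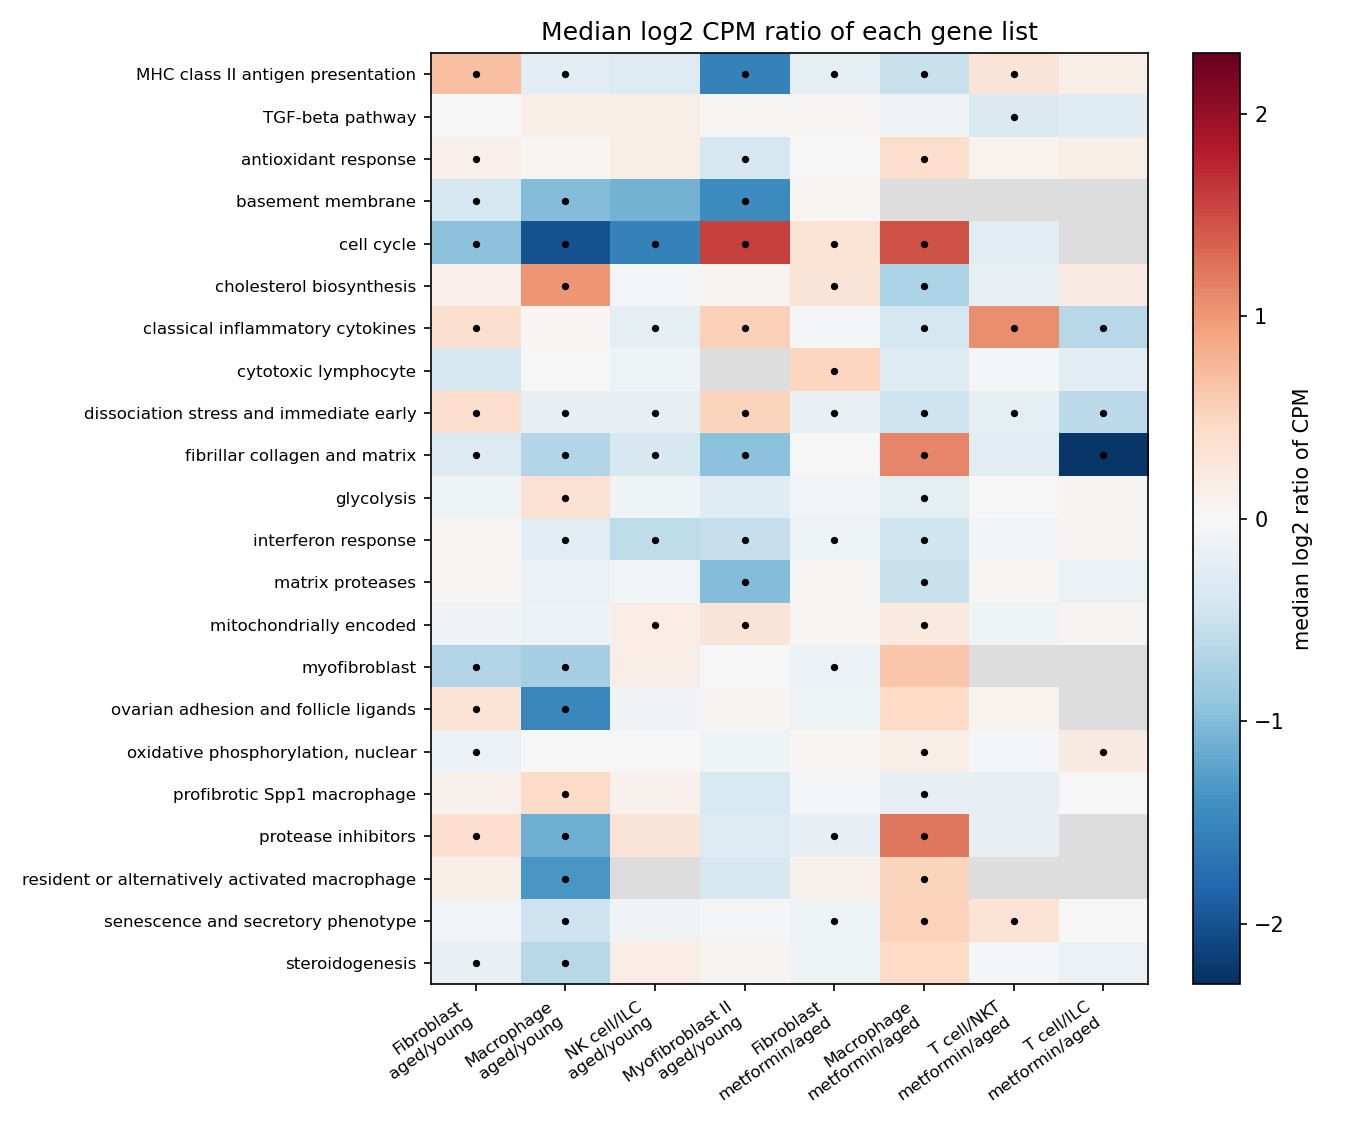
Median log2 ratio of CPM of each of 22 gene lists (rows) in the cell types named in detail (columns), coloured from blue (lower) to red (higher); a dot marks a list outside the central 95% of random lists and grey a list with fewer than 3 measured genes. Cell cycle genes range from -2.01 in macrophages with age to 1.57 in Myofibroblast II with age, where the value is -2.06 without pool B.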

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

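The test of the pools that hold Macrophage II, the look at its markers and the count of classes with lower stress genes were chosen after their results were seen. The other tests of this part were written before.

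In 5 gene groups the medians of fibroblasts and macrophages lay on opposite sides of 0 in every pool, and the difference between the cell types was not tested. With age, dissociation stress genes had a median of 0.41 in fibroblasts and -0.20 in macrophages, a difference of 0.607. Ovarian adhesion and follicle ligand genes stood at 0.32 and -1.50 with age, a difference of 1.82. Protease inhibitor genes stood at 0.39 and -1.12 with age, a difference of 1.51. With metformin, cholesterol biosynthesis genes stood at 0.29 in fibroblasts and -0.72 in macrophages, a difference of 1.01. Senescence genes stood at -0.12 and 0.53 with metformin, a difference of -0.652.

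The fibroblast share was lower with metformin than in the untreated aged condition over all pools, but aged fibroblasts made up 52.4%, 45.2% and 28.5% of aged cells in pools A, B and C, although the labels describe 1 suspension, and the ratio of metformin to aged was 1.02 in pool C. Young fibroblasts that carried the tag of the aged condition in pool A are argued against by the position of those cells on a score of 100 genes, where 0 is young and 1 is aged in pool C, which was 0.988 (0.808 to 1.25). Extra shallow droplets in pool A are argued against by the median UMIs of its aged fibroblasts, which were 1.15 times those of pool C (1.05 to 1.26). How the cells were divided, captured and tagged, and whether the pools hold different mice, stays open, and so does an effect of treatment, which was not tested.

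Macrophage II made up 102 cells with metformin and 5 cells in the other conditions together. A single pool as their source is argued against, since the pool with most of them held 36.3% (27.0 to 46.4). Doublets of macrophages with another cell type are left open by a median depth 1.04 times that of Macrophage/Monocyte I, whose interval of 0.907 to 1.18 reaches past the bound set for excluding them. Markers of the class, picked because other classes nearly lack them, bear on this too. Cxcl13, Cd300e and Lipg were at 498, 635 and 615 CPM, against means of 0.603, 3.62 and 6.19 CPM over the other classes. A mixture of deposited classes would not reach such levels, which argues against doublets as the source of these genes. Lipg had UMIs in only 43 of 344 metformin macrophages, so doublets among the other cells stay open. Cells from only 1 of the 3 pooled animals cannot be told apart from cells of all 3, because a condition has 1 tag. An effect of metformin stays open and was not tested.

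The median of dissociation stress and immediate early genes was below the random lists with metformin in fibroblasts, macrophages and both T cell classes, although in T cell/NKT only 6 of 16 genes had an interval below 0 and 1 had one above. With cells thinned to 1000 UMIs the medians of these 4 classes ran from -0.71 to -0.17. Thinning keeps each cell's expected CPM, so it could hardly undo an effect of depth and does not decide on one. Median depths with metformin and in the aged condition were 3636 and 3629 UMIs in fibroblasts and 4726 and 4912 in macrophages. In T cell/ILC they were 1851 and 1852, and in T cell/NKT 1922.5 and 2033. The median of the stress genes lay below 0 in 8 of 8 classes measured, from -1.04 in B cells of class I to -0.07 in NK cells and in Myofibroblast II. In 2 of these classes, NK cells (percentile 9.5, with 2 genes above and 2 below 0 by their intervals) and follicular granulosa cells (percentile 9.75, with 3 and 6), it lay within the random lists. Handling of the 1 suspension of each condition cannot be told apart from treatment, because both change together. The young and aged suspensions are open to the same doubt, with medians of 0.41 in fibroblasts and -0.20 in macrophages.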

How the results depend on the processing

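Leaving out the top cell of a gene, taking Macrophage/Monocyte I alone, adding myofibroblasts to fibroblasts, leaving fibroblasts out of the denominator, and all values of follicular granulosa cells were chosen after seeing the data. No paired test was run, because the labels describe 1 suspension per condition and name no mice. Each pool holds all 3 conditions and ratios within a pool were computed, so a fit with the pool as a block can be made, and it would need pools of different mice, which is open. The edgeR and DESeq2 tests, a replicate block and a fit with no filter were not run, since tags name conditions. With no test, a value is called moved when it left its counting interval or, for a list, the spread of its pools. Of 357 share ratios under alternatives, 38 moved and 1 turned, of 1504 gene ratios 230 moved and 15 turned, and of 794 list medians 98 moved and 20 turned. No share or gene ratio moved with cells of at least 1000 UMIs or under 10% mitochondrial UMIs, and no share ratio with equally weighted pools or, for 8 of them, rebuilt classes. Rebuilt classes were matched to the deposited ones after seeing the data, and no rebuilt value was computed for follicular granulosa cells, most of which, over the 3 conditions together, fell in clusters without a name. TMM factors shifted follicular granulosa cells by -0.19 with age and all other classes by less than 0.1. The minimum of UMIs decides which genes are named: of 8 fibroblast genes, 6 were shared at 20 UMIs and 3 at 200 with age, and 3 and 3 with metformin. At 200 UMIs, 2 of 7 genes were shared in NK cells with age. With metformin 1 of 6 was shared in T cell/NKT and 4 of 5 in T cell/ILC. Except where the denominator or the set of cells itself was changed, the cause was not tested for the values that follow.

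Share ratios with age, over left-out pools, ran from 1.45 to 1.79 for fibroblasts, 3.11 to 4.20 for T cells and 0.169 to 0.259 for the class deposited as luteinized granulosa. Among cells other than fibroblasts they were 4.50 for T cells, 0.416 for macrophages, 0.441 for follicular and 0.260 for the class deposited as luteinized granulosa. With metformin, fibroblasts ran from 0.60 to 0.771 over left-out pools and stood at 0.888 among non-immune cells, where follicular granulosa cells stood at 1.25. Macrophages stood at 0.949 and T cells at 1.26 among immune cells, and at 1.06 and 1.41 among cells other than fibroblasts.

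With age, over left-out pools, fibroblast Col1a1 ran from -0.54 to -0.43, Col3a1 from -0.74 to -0.65, the collagen list from -0.38 to -0.25 and the antioxidant list from -0.024 to 0.20. Macrophage Spp1 ran from 1.66 to 2.46. In Myofibroblast II, Cd74 ran from -2.46 to 0.54, Cenpf from -1.60 to 7.09, cell cycle from -2.06 to 5.53 and MHC class II from -1.70 to 0.60. In NK cells, Col3a1 ran from -2.04 to 0.37 and the collagen list from -0.93 to 0.20. The Spp1 macrophage list in follicular granulosa cells ran from -0.42 to 0.026, and stood at 0.030 with cells under 10% mitochondrial UMIs and 0.24 with 5 UMIs added. As the mean over cells, Col1a1 was at -0.62, Col1a2 at -0.48 and Col3a1 at -0.93. Thinned, Col1a2 was at -0.50, Col3a1 at -0.94 and Spp1 at 2.02. Without the top cell, Spp1 was at 1.80 and Cenpf at -1.84. With 5 UMIs added, macrophage basement membrane was at 0.48, collagen at 0.049 and steroidogenesis at 0.51.

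With metformin, over left-out pools, fibroblast Col3a1 ran from -0.20 to -0.053, Cd74 from -0.35 to 0.012, Nkg7 from -0.28 to 1.25, cytotoxic genes from -0.091 to 0.93 and MHC class II from -0.39 to 0.0055. Macrophage Spp1 ran from -2.36 to -1.04, the T cell/ILC cytokine list from -0.67 to 0.32, T cell/NKT Ccl4 from -0.028 to 1.02, the TGF-beta list there from -0.31 to 0.22, and the granulosa myofibroblast list from -0.074 to 0.75. Thinned, fibroblast Col1a2 was at -0.075, Col3a1 at 0.035, Hmgcs1 at -0.031, Nkg7 at -0.12 and granulosa Aldoa at 0.030. With myofibroblasts added, Col1a2 and Col3a1 were at -0.21. As the mean over cells, Col3a1 was at 0.045 and granulosa Selenop at -0.64. In Macrophage/Monocyte I alone, Klra17 was at -1.30, Spp1 at -1.10, Apoe at 0.18, cytokines at 0.046, the Spp1 list at 0.11 and nuclear oxidative phosphorylation at -0.0030. Without the top cell, Spp1 was at -1.25. In T cell/NKT, the TGF-beta list was at 0.10 over genes with at least 100 UMIs, and the senescence list at -0.057 with 5 UMIs added.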

Other observations

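The follicular granulosa values, the values within rebuilt clusters and the choice of the clusters named here were chosen after seeing the data, and no test was run in this part. Follicular granulosa cells, which make oestrogen from theca cell androgens, had higher steroidogenesis, cholesterol biosynthesis and glycolysis genes in the aged condition (131 cells) than in the young (996 cells). Steroidogenesis genes were higher for 15 of 16 (median 2.06), with Hsd3b1 at 2.36 (2.28 to 2.44) and Hsd17b1 at 2.06 (1.96 to 2.16), all 18 cholesterol biosynthesis genes were higher (1.33), with Fdps at 1.39 and Msmo1 at 1.47, and all 16 glycolysis genes (1.0), with Aldoa at 0.99 and Ldha at 1.04 (0.39 with thinned cells). Markers of theca cells had a median of 2.21 in these cells, of luteal cells 1.99, of stromal fibroblasts 1.87, of granulosa cells 1.37 and of macrophages -1.13. The mix of rebuilt clusters within the class differed by condition. A granulosa-like cluster led by Inhba, with Hsd17b1 and Lhcgr among its leading genes, held 1.41% of its young, 32.1% of its aged and 29.5% of its metformin cells. Clusters without a name led by Coch (45.6%, 22.1% and 34.6%) and by Aard (31.5%, 8.40% and 8.33%) and a stromal fibroblast-like one led by Kcnk2 (2.81%, 14.5% and 8.33%) held most of the others. A granulosa-like cluster led by Amh, with Ube2c among its leading genes, held 13.3%, 11.5% and 5.13%. TMM factors would shift these values by -0.19. Collagen and matrix (0.83), interferon response (0.55), ovarian adhesion and follicle ligand (0.55) and cell cycle genes (0.52; 0.15 without pool B) also lay above the random lists, and MHC class II (-1.04), matrix protease (-0.66; -0.15 with 5 UMIs added), dissociation stress (-0.25; -0.088 without pool B) and Spp1 macrophage genes (-0.16) below. The last list stood at 0.026 without pool C, 0.030 with cells under 10% mitochondrial UMIs and 0.24 with 5 UMIs added. Among the MHC class II genes Cd74 was at -1.59 and H2-Aa at -1.58, the latter at -0.98 without pool A and -2.34 without pool B. With metformin (156 cells) all 16 cell cycle genes were lower than in the untreated aged condition (median -1.14; -1.85 without pool B), with Top2a at -1.54 (-2.35 without pool B) and Ube2c at -1.78 (-2.83 without pool B), and 15 of 16 glycolysis genes (-0.53), with Aldoa at -0.42 (0.030 with thinned cells) and Ldha at -1.1 (-0.52 with thinned cells). Cholesterol biosynthesis genes were lower too (-0.33). All 5 MHC class II genes were higher (0.89; 0.16 without pool A), with Cd74 at 2.0, or 0.98 without 1 cell, as were resident macrophage genes (0.70), with Gas6 at 0.89 (0.34 with thinned cells) and Selenop at 0.72 (-0.64 as the mean over cells), beside macrophage markers at 1.61 and theca markers at 0.59. Myofibroblast (0.39), steroidogenesis (0.19) and mitochondrially encoded genes (0.13) lay above the random lists with all pools. Over left-out pools the first ran from -0.074 to 0.75 and the second from 0.0086 to 0.049. Smooth muscle markers had a median of 0.46 in this comparison, luteal markers 0.19 and granulosa markers -0.35.

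Clustering the cells again gave several stromal clusters with different shares. A stromal fibroblast-like cluster led by Lrat held 11% of young, 25.1% of aged and 17.3% of metformin cells, one led by Kcnk2 held 4.95%, 15.1% and 9.91%, and one led by Col1a1 held 9.65%, 4.03% and 2.24%. With metformin, Col1a1 in the deposited fibroblasts of the Col1a1 cluster was at 1095 against 782 CPM (0.49, 0.34 to 0.64; 81 and 112 cells), whereas it stood at -0.23 (-0.33 to -0.12; 638 and 738 cells) in those of the Lrat cluster and at -0.24 (-0.58 to 0.10; 356 and 423 cells) in those of the Kcnk2 cluster. Col1a2 in these 3 clusters was at 0.06 (-0.03 to 0.16), -0.21 (-0.27 to -0.14) and -0.03 (-0.19 to 0.12), and Col3a1 at 0.11 (-0.01 to 0.23), -0.0042 (-0.10 to 0.09) and 0.12 (-0.20 to 0.43).

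A macrophage-like cluster led by Fcgr4, Cd300e and Cxcl13, which also held Lipg and Klra17 among its leading genes, made up 2.80% of metformin cells (2.29 to 3.38), 0.034% of aged cells and 0.039% of young cells. A T cell-like cluster led by Trdc, the constant region of the T cell receptor delta chain, with Il17a among its leading genes, held 0.551% of young, 4.03% of aged and 6.37% of metformin cells. A cluster without a name, led by Spp1, Gpnmb and Mmp12, held 1.12%, 0.806% and 0.479% of all cells. Of its 127 cells, 125 were deposited as Macrophage/Monocyte I. That class held 21.6% of young, 6.81% of aged and 6.45% of metformin cells, so the shares of this cluster do not give its fraction within macrophages. Another cluster without a name, led by Cxcl9 and interferon response genes such as Ifit2 and Rsad2, held 50 of 7620 young cells (0.656%), 0 of 2979 aged cells, which by the limit of 3 counts allows a share of up to 0.101%, and 0 of 3754 metformin cells, which allows up to 0.080%.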
